A study of Mus musculus and Homo sapiens with 22 samples.

How the data were processed

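RNA structure was probed by icSHAPE in chromatin, nucleoplasm and cytoplasm fractions of HEK293, a human embryonic kidney cell line, and of mouse embryonic stem (mES) cells. In icSHAPE, the reagent NAI-N3 acylates the 2′-hydroxyl of flexible nucleotides, and a higher score marks a nucleotide that reacted more. The reagent was given to living cells (in vivo) or to RNA that had been purified, denatured and refolded (in vitro). Lin28A-bound RNA was mapped by irCLIP, an ultraviolet crosslinking and immunoprecipitation method, in Mettl3 wild-type (WT) and knockout (KO) mES cells. Mettl3 is the catalytic subunit of the enzyme complex that writes N6-methyladenosine (m6A) on mRNA. Of the 22 samples, 14 had a processed file: 12 icSHAPE files and 2 irCLIP site lists. The 6 solvent-control icSHAPE samples and the 2 anti-GFP irCLIP controls were not analysed here.

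Each group held 1 sample. The labels state about 200000000 reads per replicate for the icSHAPE libraries of both cell lines, and how many reads stand behind each file and whether replicates were combined within it are not given in the sources used here. The compartments of a cell line were not treated as replicates and no test between samples was run, so no p-value, standard error or replicate check is given, and each interval printed covers only the counting of transcripts or sites within a file. Kit and sequencer also differed between the cell lines, per the labels' protocols: the HEK293 and mES libraries used different rRNA removal kits and different sequencer models. Cell line and library batch cannot be told apart in these data.

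Each icSHAPE file as deposited held, per transcript, an identifier, a length, an abundance signal whose unit is not given in the sources used here, and 1 score per nucleotide from 0 to 1 or a missing value. The score deposited by the authors was missing for the first 6 and last 30 nucleotides of every transcript. Each site list as deposited held positions in steps of 50 nt, a strand, a score and a p-value per site. The p-value deposited by the authors followed the score of each 50-nt site, and no site had a p-value above 1.1e-05. The site caller, its control and its threshold are not given in the sources used here. Site scores are the authors' own values and were used only to describe, rank or filter sites within a list. Bowtie2, UMI-tools and the genome builds hg38 and mm10 are named in the submitters' processing notes, with no versions of the tools.

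For each pair of icSHAPE files, the mean score per transcript was taken over nucleotides scored in both files, for transcripts with at least 100 such nucleotides. The percent of transcripts with the higher mean in the first file was given with its exact (Clopper-Pearson) 95% binomial interval, and the median difference with an interval from order statistics. These intervals treat transcripts as independent, but transcripts share genes and sequence, so the intervals are too narrow. Each comparison was split into odd and even nucleotides as a check within the files. The Gini index measured how unevenly the score was spread along a transcript, from 0 (even) upward. Profile similarity was Pearson's r across the shared nucleotides of a transcript. Abundance ratios were log2 ratios after a pseudocount of 1 was added. The signal at a period of 3 nt was the power of the profile at that frequency divided by the mean power at 24 neighbouring frequencies, for transcripts with at least 500 shared nucleotides. Control frequencies of 0.24 and 0.43 per nt were treated alike.

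The files did not pair the transcript identifiers with gene names, so the 18 gene lists fixed before the data were examined could not be applied to icSHAPE. No isoform was preferred for the same reason: all transcripts were used where 1 per gene had been intended. Among 26879 HEK293 and 17092 mES transcripts, 206 and 366 shared a 60-nt pattern of zero and non-zero scores with another transcript. As an alternative, 1 transcript per such family was tried. This left 26710 HEK293 and 16776 mES families, so few transcripts were removed and most values had little room to change. Analyses that needed sequence or transcript models (mRNA regions, codon profiles, m6A motifs, agreement between species, GGAG content, and icSHAPE around Lin28A sites) were not run.

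Lin28A sites were placed on RefSeq genes of GRCm38.p6, the assembly behind mm10, which gives gene bounds without exons or strand. A site overlapping a single gene was assigned to it, and a site over a single small RNA gene that also overlapped other genes was assigned to the small RNA. Sites over several small RNA genes of the same class counted for the class only. Of 10990 WT and 11285 KO sites, 461 and 480 overlapped several genes and were left unassigned, and 1124 and 1126 overlapped none. Sites of the lists were called overlapping when they shared at least 1 nt on the same strand. The chance level came from 100 random placements of the sites within the bodies of their genes, introns included. For each gene list with 5 or more members bearing a site, the KO percent of its sites was ranked among 10000 random lists of the same size matched on decile of sites. Gene symbols were matched without regard to case and then through synonyms.

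The rule for named genes was fixed before the data were examined: the 10 genes with the most sites in each list, the 5 with the largest difference each way, members of the fixed lists, and Mettl3, Lin28a, Malat1 and Gapdh. For icSHAPE, extremes were taken among transcripts with at least 300 shared nucleotides and the same sign over odd and even nucleotides. Alternatives fixed before the data were examined included other nucleotide minimums of 50 and 300, ranks of scores within a file, medians, an abundance filter of 10, a pseudocount of 0.1, a reciprocal overlap of 50%, and sites at or above their list's median score. Other alternatives, length classes, the 3-nt period and unshared sites by class were chosen after seeing the data. The ranking of gene lists by KO percent of sites was also chosen then, after ratios of site scores between the genotypes had been computed, seen and set aside.

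The code of the steps was checked on simulated data. For the mean score difference and the site overlap the right answer was fixed by construction, so these checks cover the code and not noise. For the mean score difference in the in vitro cytoplasm files, all 200 changed transcripts had the right sign among 8477 in HEK293 and among 5709 in mES cells. For the 3-nt period in shuffled in vivo cytoplasm profiles, all 200 of 1000 profiles with an added wave exceeded a ratio of 5 in each cell line. Of the 800 without a wave, 15 in HEK293 and 6 in mES cells did so. For site overlap in the WT list, 600 of 600 shifted sites and 0 of 400 opposite-strand sites were found. The work used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.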

Results

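The data comprised icSHAPE scores for chromatin, nucleoplasm and cytoplasm of HEK293 and mES cells, each probed in vivo and in vitro, and Lin28A irCLIP sites from Mettl3 WT and KO mES cells. Each of the 14 files was the only file of its group. The HEK293 files held between 911595 scored nucleotides (chromatin in vivo) and 6437699 (nucleoplasm in vitro). The mES files held between 1980997 (chromatin in vitro) and 12871282 (nucleoplasm in vitro). Transcripts with at least 100 scored nucleotides numbered from 1348 to 8477 in the HEK293 files and from 2080 to 9969 in the mES files. Read depth is not given in the files, and the labels' protocols state about 200000000 reads per replicate for both cell lines. Scores of exactly 0 made up between 20.3% and 47.7% of scored nucleotides in a file.

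The comparison of in vivo with in vitro probing asked how the structure of an RNA inside the cell differed from that of the same RNA refolded on its own. In HEK293 cells most transcripts had lower scores in vivo than in vitro: 38.1% (95% interval 35.4 to 40.8) were higher in vivo in chromatin, 37.6% (36.0 to 39.1) in nucleoplasm and 28.5% (26.8 to 30.2) in cytoplasm. In mES cells most had higher scores in vivo: 66.7% (64.6 to 68.7) in chromatin, 64.7% (63.6 to 65.7) in nucleoplasm and 87.2% (86.3 to 88.0) in cytoplasm. The median differences (in vivo minus in vitro) were -0.0182, -0.0142 and -0.0237 in the HEK293 fractions and 0.0264, 0.00815 and 0.0383 in the mES fractions, over 1266, 3946, 2786, 2072, 8608 and 5673 transcripts. The mean score over these transcripts lay between 0.154 (HEK293 chromatin in vivo) and 0.215 (HEK293 cytoplasm in vitro).

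The direction depended on the treatment of the scores and on the nucleotides used. Ranks were taken over all scored nucleotides of a file, so they also depend on the transcripts it held and its share of zeros. With scores replaced by their ranks within the file, the percent of transcripts higher in vivo was 40.5, 65.1 and 58.9 in the HEK293 chromatin, nucleoplasm and cytoplasm and 45.4, 59.3 and 57.1 in the mES fractions. With nucleotides above 0 in both files, it was 43.5, 51.4 and 45.2 in HEK293 and 52.0, 65.4 and 69.9 in mES cells. Over nucleotides scored in all 6 files of the cell line, HEK293 chromatin also turned, to 64.9% higher in vivo. The share of zero scores was higher in vivo in the HEK293 fractions (31.7%, 34.2% and 36.0% against 26.0%, 20.3% and 24.97%). In mES cells it was lower in vivo in chromatin (20.9% against 41.5%) and cytoplasm (34.5% against 47.7%) and nearly equal in nucleoplasm (38.0% against 38.1%).

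**Figure D1:**
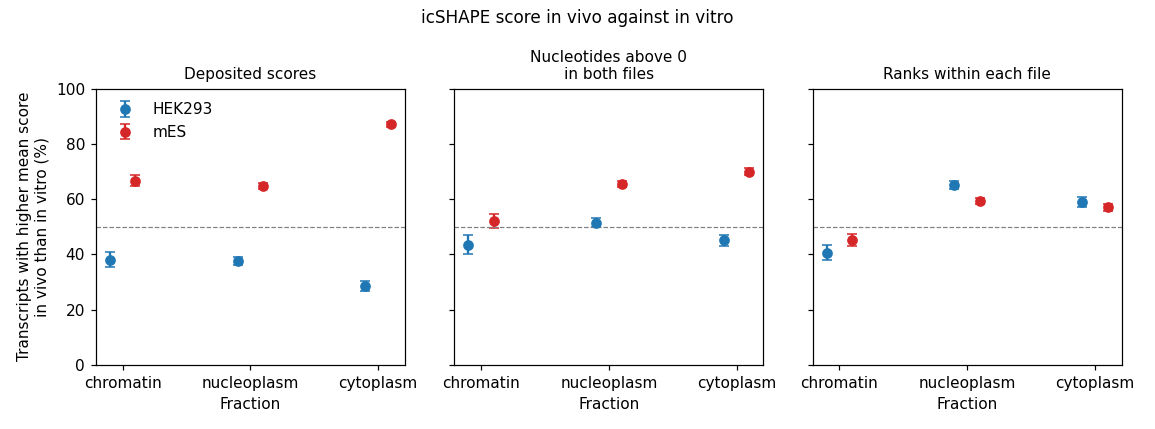
Percent of transcripts (vertical axis) with a higher mean icSHAPE score in vivo than in vitro in each fraction (horizontal axis) of HEK293 (blue) and mES cells (red), with exact 95% binomial intervals over transcripts; the dashed line marks equal numbers. With deposited scores the cell lines lay on opposite sides of the line (28.5% and 87.2% in cytoplasm), and with ranks within each file they lay close together (58.9% and 57.1%).

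Short transcripts, under 300 nt, a length class that includes many small noncoding RNAs, differed from long ones in mES cells. Among mES transcripts under 300 nt, 35.7% (27.8 to 44.1; n = 143) were higher in vivo in chromatin, 32.0% (25.5 to 39.0; n = 197) in nucleoplasm and 53.8% (45.7 to 61.8; n = 158) in cytoplasm. Among longer mES transcripts the values were 69.0%, 65.4% and 88.1%. In HEK293 cells the short class lay at 37.0%, 30.7% and 24.5% and the long class at 38.3%, 37.8% and 28.7%, and with ranks the short class was at 63.3% in nucleoplasm and 73.4% in cytoplasm. The mES short class turned as well: in cytoplasm it lay at 22.2% with ranks and at 31.4% over nucleotides scored in all 6 files, and in nucleoplasm at 52.2% (n = 23) over nucleotides above 0. The split by length was chosen after the data were examined.

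Transcripts measured in all 3 compartments kept 1 direction more often than independent directions would give, but most did not keep it. Of 434 such HEK293 transcripts, 123 were lower in vivo in every compartment and 61 were higher in every compartment, where independent directions would give 85.1 and 26.9. Of 1044 mES transcripts, 416 were higher and 73 lower in every compartment, where independent directions would give 343.4 and 22.6. The files do not pair transcripts with gene names. In the cytoplasm, the HEK293 transcript ENST00000487233 (2225 nt) had the highest difference, with a mean score of 0.397 in vivo and 0.0513 in vitro over 321 nucleotides, and ENST00000409170 (562 nt) the lowest, with 0.0604 and 0.257 over 318. In mES cytoplasm, the highest was ENSMUST00000131011 (540 nt), with 0.2399 in vivo and 0.114 in vitro over 406 nucleotides, and the lowest ENSMUST00000133785 (2858 nt), with 0.120 and 0.335 over 406.

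The shape of the score profile along each transcript was partly kept between living cells and refolded RNA. The median Pearson r across nucleotides lay between 0.529 (HEK293 cytoplasm) and 0.606 (HEK293 nucleoplasm). Between compartments the median r lay between 0.663 and 0.761 in vivo and between 0.570 and 0.721 in vitro. These values were above the highest of the former range, except for HEK293 chromatin against cytoplasm in vitro (0.570). In HEK293 cells the scores were more unevenly spread in vivo, with a higher Gini index for 63.9% of transcripts in chromatin, 80.9% in nucleoplasm and 83.4% in cytoplasm. In mES cells they were more evenly spread in vivo, with a higher index for 13.3%, 41.0% and 2.66% of transcripts. The direction in HEK293 chromatin and nucleoplasm depended on the zeros, and that in cytoplasm was kept: over nucleotides above 0 in both files, the index was higher in vivo for 33.0%, 43.5% and 55.5% of HEK293 transcripts and for 24.9%, 42.6% and 17.8% of mES transcripts. Odd and even nucleotides of a transcript gave the same direction of the in vivo minus in vitro difference for between 81.9% and 93.5% of transcripts, which checks nucleotide sampling within a file and not culture variation.

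A repeat every 3 nt, the length of a codon, ran through the score profiles and was stronger in vivo for most transcripts of each pair. The signal at a period of 3 nt was stronger in vivo than in vitro for 56.7% (51.3 to 61.9), 69.0% (66.8 to 71.1) and 74.6% (72.1 to 77.02) of transcripts in HEK293 chromatin, nucleoplasm and cytoplasm. In mES cells the values were 63.6% (60.6 to 66.6), 68.1% (66.9 to 69.4) and 70.7% (69.2 to 72.2). A ratio above 5 was reached by 16.5%, 35.2% and 32.9% of HEK293 transcripts in vivo against 11.1%, 22.5% and 8.56% in vitro, and by 23.8%, 36.7% and 40.2% of mES transcripts in vivo against 12.3%, 24.4% and 23.8% in vitro. In HEK293 chromatin the median ratio was slightly lower in vivo (1.18 against 1.21), unlike in the other pairs. Among transcripts no more abundant in vivo, the chromatin values were 52.4% (46.0 to 58.8) in HEK293 and 54.2% (48.4 to 60.02) in mES cells, and both intervals include equal numbers. Compared directly in vivo, the period was stronger in nucleoplasm than in cytoplasm for 61.2% (59.6 to 62.7; n = 3913) of mES and 46.9% (43.8 to 50.1; n = 965) of HEK293 transcripts, and in vitro for 57.7% (56.0 to 59.5) and 61.0% (59.0 to 63.0). It was stronger in chromatin than in cytoplasm in vivo for 52.5% (48.4 to 56.7) of mES and 51.5% (41.3 to 61.7) of HEK293 transcripts, which includes equal numbers. At the control frequencies in the 6 pairs in vivo and in vitro no more than 1.42% of transcripts reached 5 in either file. The period was examined after the data were seen.

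**Figure D2:**
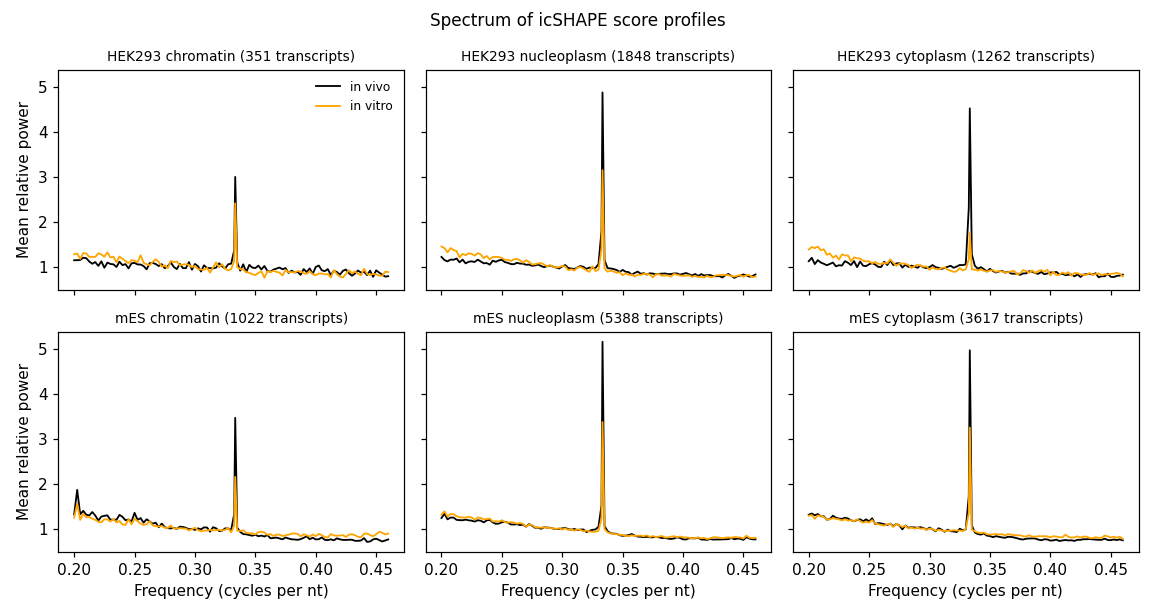
Mean relative power of icSHAPE profiles (vertical axis, each transcript scaled to a mean of 1) against frequency in cycles per nt (horizontal axis) for each cell line and fraction, in vivo (black) and in vitro (orange). A narrow peak stands at a period of 3 nt in every panel and is taller in vivo, where 74.6% of HEK293 and 70.7% of mES cytoplasmic transcripts had the stronger signal.

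The comparison of compartments asked whether an RNA was folded differently on chromatin, in the nucleoplasm and in the cytoplasm. In vivo and with the deposited scores over shared nucleotides, chromatin RNA of mES cells was more reactive than the same transcripts elsewhere: 76.96% (75.2 to 78.7; n = 2305) of transcripts had higher scores in chromatin than in nucleoplasm and 63.6% (61.1 to 66.0; n = 1530) higher than in cytoplasm. In nucleoplasm 29.4% (28.4 to 30.5; n = 7398) were higher than in cytoplasm. In HEK293 cells, 50.4% (46.3 to 54.5; n = 587) were higher in chromatin than in nucleoplasm, 60.1% (55.2 to 64.8; n = 421) higher in chromatin than in cytoplasm and 59.1% (57.0 to 61.1; n = 2238) higher in nucleoplasm than in cytoplasm. With ranks, the same 3 values were 58.3%, 51.4% and 47.7% in mES cells and 72.4%, 69.8% and 47.5% in HEK293 cells, which turned the HEK293 nucleoplasm comparison. With all nucleotides scored in each file, 41.1% of HEK293 transcripts were higher in chromatin than in nucleoplasm. The mES excess of chromatin over cytoplasm was nearly lost with ranks (51.4%) and over all scored nucleotides (51.1%).

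Refolded RNA differed between compartments as well. In vitro, 18.3% (15.9 to 20.9; n = 977) of HEK293 transcripts were higher from chromatin than from nucleoplasm, 28.6% (25.3 to 32.1; n = 710) higher from chromatin than from cytoplasm and 44.5% (43.2 to 45.7; n = 6151) higher from nucleoplasm than from cytoplasm. In mES cells the values were 28.7% (26.6 to 30.9; n = 1737), 48.6% (45.4 to 51.9; n = 942) and 66.2% (64.9 to 67.5; n = 5218). With ranks the values were 64.5%, 64.1% and 35.4% in HEK293 and 30.5%, 17.7% and 25.8% in mES cells, so 3 of the 6 comparisons turned. Among transcripts with abundance values within 1.5 times, nucleoplasm exceeded cytoplasm for 72.2% in HEK293, and chromatin exceeded cytoplasm for 71.0% in mES cells.

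By the abundance values, short RNAs lay more toward chromatin than long ones did. In the in vivo files, transcripts under 300 nt had a median log2 ratio of chromatin over cytoplasm of 0.81 (n = 798) in HEK293 cells, against -2.08 (n = 1340) for longer transcripts. In mES cells the medians were 2.76 (n = 612) and -1.34 (n = 5783). The in vitro files gave 2.05 and -0.67 in HEK293 cells and 4.45 and -1.89 in mES cells. Chromatin over nucleoplasm separated the classes in the same direction, with a difference (short minus long) of 3.15 and 2.00 in the HEK293 and mES in vivo files and 2.12 and 2.23 in the in vitro files. Nucleoplasm over cytoplasm did so in mES cells (1.92 in vivo, 3.24 in vitro), while HEK293 gave -0.35 in vivo and 0.15 in vitro. The unit of the abundance value is not stated, so only the classes were compared with each other, and the length classes were chosen after seeing the data. Transcripts of a pattern family were counted separately, and no alternative with 1 transcript per family was computed for these ratios. The largest family held 81 HEK293 and 184 mES transcripts, and its share of the short class was not examined.

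**Figure D3:**
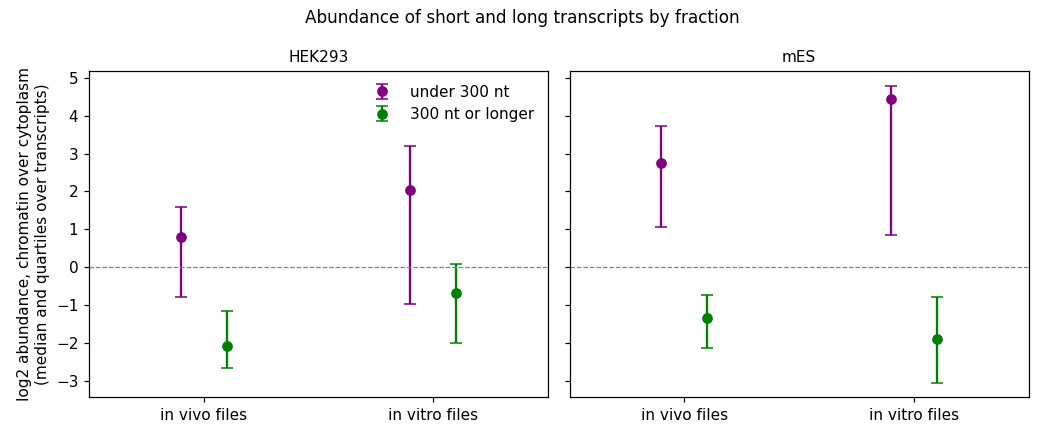
Median log2 abundance ratio of chromatin over cytoplasm (vertical axis, pseudocount of 1) for transcripts under 300 nt (purple) and longer ones (green) in the in vivo and in vitro files (horizontal axis) of HEK293 and mES cells; bars give quartiles over transcripts. Short transcripts lay above long ones in each panel, at 2.76 against -1.34 in the mES in vivo files.

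The irCLIP comparison asked where the RNA-binding protein Lin28A, an inhibitor of let-7 microRNA maturation that also binds many mRNAs, sat in mES cells with and without Mettl3. The lists held 10990 WT and 11285 KO sites, most of them 50 nt wide (86.0% and 85.5%). Of the WT sites, 75.1% (74.3 to 75.9) overlapped a KO site, and 72.9% (72.1 to 73.7) of the KO sites overlapped a WT site. For sites assigned to 1 gene the values were 74.6% and 72.2%, and random placement of these within the same gene bodies gave means of 7.24% and 6.89%. Introns were included, so this level takes no account of exons or of RNA level. Of the sites with a score of at least 50 in their own list, 99.5% (of 1472) and 99.8% (of 1372) overlapped the other list. At least 1 site fell in 5157 genes, of which 3683 were in both lists, 602 in the WT list only and 872 in the KO list only, and the genes of a single list had a median of 1 site. Mettl3 had no site in either list, and site lists do not measure its level, so the genotype labels were not checked here.

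Protein-coding genes held 78.5% of WT and 78.0% of KO sites, with 8632 and 8804 sites, a KO to WT ratio of 1.02 that was 0.965 among sites at or above each list's median score. The genes with the most sites were largely the same in both genotypes. In WT cells they were Gm33272, an annotated long noncoding RNA (33 sites), Macf1, a cytoskeletal crosslinker (32), Tet1, a 5-methylcytosine dioxygenase (31), Nedd4, a ubiquitin ligase (30), Igf2bp1, an mRNA-binding protein (30), Flna, an actin crosslinker (30), Nucks1 (29), the translation factor Eif4g2 (27), Fn1, which encodes fibronectin (24), and the deubiquitinase Usp9x (24). In KO cells the leading counts were Fn1 (39), Nedd4 (32), Gm33272 (31), Tet1 (29), Igf2bp1 (29), the ubiquitin ligase Trip12 (28), Usp9x (26), Flna (25), the importin Kpnb1 (25) and Nucks1 (24). Eif4g2 also had 24 KO sites, and Akap12, named after its values were seen, also had 24 WT sites, so the last place in each list was tied. Nedd4 had 2 more sites in the KO list, but 8 fewer among sites at or above each list's median score, and Gm33272 and Eif4g2 likewise turned direction there. Lin28a itself had 6 WT and 5 KO sites. The nuclear long noncoding RNA Malat1 had 9 sites in each list, covering 6150 nt in both, and Gapdh had 2 and 1.

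The largest differences in site number lay in a few genes. Fn1 (chromosome 1, 71585473 to 71653280, GRCm38.p6) had 24 WT and 39 KO sites, a KO share of 61.9% (48.8 to 73.9) where all sites gave 50.7%. Mybbp1a, a nucleolar protein, had 12 and 21, Mdn1, a ribosome assembly ATPase, 7 and 16, Cenpf, a kinetochore protein, 2 and 11, and Gm52481 1 and 9. In the other direction, Col18a1 (chromosome 10, 77052178 to 77166530), which encodes a basement membrane collagen, had 20 WT and 7 KO sites, a KO share of 25.9% (11.1 to 46.3). Hspg2, the basement membrane proteoglycan perlecan, had 22 and 10, Macf1 32 and 21, the import receptor Ipo5 21 and 12, and Grb10 (chromosome 11, 11930499 to 12037428), an adaptor of insulin receptor signalling, 11 and 0. Of 371 genes with at least 10 sites over both lists, 2 had a counting interval above the share over all sites (Cenpf and Gm52481) and 4 below it (Col18a1, Grb10, Hspg2 and Snrnp200, which had 11 and 2 sites). Exact 95% intervals may miss a common share in up to 5% of genes by counting error alone. These 6 genes are fewer than that. The 5% holds for independent sites, but 75.1% of WT sites overlapped a KO site, which draws the shares together. The count therefore does not decide whether genes differed. Sites overlapping none in the other list numbered 4 in WT and 20 in KO for Fn1 and 1 and 10 for Mdn1. For Col18a1 they numbered 13 and 0, and for Hspg2 13 and 1. Snrnp200 was chosen after its values were seen.

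**Figure D4:**
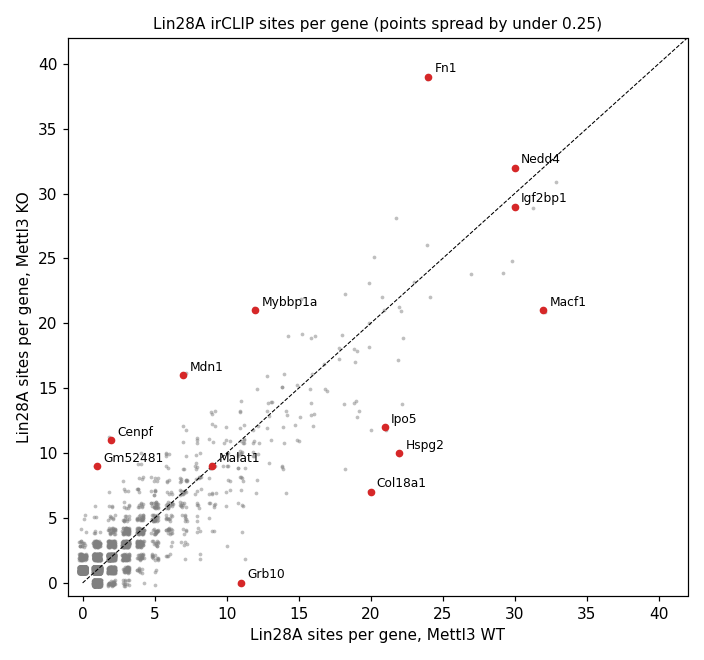
Lin28A irCLIP sites per gene in Mettl3 WT (horizontal axis) and KO mES cells (vertical axis); each grey point is a gene, spread by under 0.25 for visibility, red points are named genes and the dashed line marks equal counts. Most genes lay near the line, with Fn1 (24 and 39) above it and Col18a1 (20 and 7) and Grb10 (11 and 0) below.

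Lin28A sites lay in many housekeeping and pluripotency genes in both genotypes. Sites were placed within gene bounds without exons or strand. Counts given for mRNAs here and in the next paragraph may therefore include introns and the opposite strand. Eno1, for example, had 5 plus-strand and 2 minus-strand sites over both lists. Translation factor mRNAs held sites in all 22 of their members, with 175 WT and 166 KO sites (Eef2 22 and 21, Eif4g1 18 and 17, Eif3a 16 and 13). Of 46 ribosomal protein mRNAs, 32 held sites, 90 WT and 98 KO in total (Rpl4 11 and 10, Rpl13a 9 and 9). Splicing factor and hnRNP mRNAs had 188 and 192 sites over 29 of 33 members (Hnrnpu 19 and 18, Sf3b1 15 and 19), and chaperone mRNAs 180 and 175 over 17 of 20 (Hspa4 18 and 19, Cct2 16 and 12). That list was fixed as cytosolic but also held the mitochondrial chaperones Hspa9 (17 and 15), Hspd1 (11 and 8) and Hspe1 (3 and 3). Endoplasmic reticulum and secretory pathway mRNAs had 127 and 129 over 20 of 23 (Canx 21 and 22, Hsp90b1 16 and 19), and glycolysis and cytoskeleton mRNAs 107 and 97 over 18 of 24 (Pkm 11 and 7). Cell cycle and replication mRNAs had 100 and 109 over 23 of 26 (Top2a 21 and 21), and histone mRNAs 33 and 36 over 15 of 15. The histone list was fixed as replication-dependent but also named H1f0, a linker histone that is not.

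Pluripotency factor mRNAs had 74 WT and 79 KO sites over 24 of 31 members, with 9 members higher in KO and 7 higher in WT (Pou5f1 6 and 7, Nanog 2 and 6, Esrrb 4 and 9, Trim71 14 and 9). Chromatin regulator mRNAs had 154 and 135 over 23 of 27 (Chd4 23 and 23, Trim28 18 and 18, Smarcc1 11 and 6), and short-lived regulatory mRNAs 27 and 24 over 8 of 28 (Mcl1 11 and 10, Mycn 7 and 3). The m6A writer, eraser and reader mRNAs had 39 and 42 over 8 of 19, most of them in Igf2bp1. Markers of fibroblasts, extraembryonic cells and early lineages had 37 and 47 over 5 of 26, mainly from Fn1, with Sparc at 0 and 3 and Lamb1 at 8 and 4. Of 12 loci of let-7 and other microRNAs, Mirlet7d, Mirlet7f-1, Mirlet7g and Mirlet7i each held 1 site in both lists and Mir98 held 1 in KO only. Nuclear-retained long noncoding RNAs had 15 and 18 over 7 of 12 (Neat1 1 and 5), snoRNA hosts and other exported noncoding transcripts 7 and 5 over 4 of 11, abundant small structured RNAs 14 and 16 over 13 of 18, and mitochondrially encoded mRNAs 30 and 22 over 5 of 13 (ND5 14 and 9). Among 10000 matched random lists, the KO share of the lists' sites lay between percentile 6.14 (mitochondrially encoded mRNAs) and 87.7 (the lineage markers), and chromatin regulators stood at 11.96. For the mitochondrial list, sites of the KO list were wider, and the covered length was 3900 nt in WT and 4000 nt in KO. Sites that also covered a tRNA or several genes were not counted for it. Examples are the WT site from 14101 to 15250, assigned to TrnE, and the KO site from 2151 to 4800, left unassigned. Strand was ignored, and ND5 had 9 plus-strand and 14 minus-strand sites over both lists. The mitochondrial counts and percentile therefore depend on the assignment of sites.

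Transfer RNA genes held 182 WT and 246 KO sites, a KO to WT ratio of 1.35, and snoRNA genes 170 and 199, a ratio of 1.17. The covered length was 13550 nt in WT and 18650 nt in KO for tRNA genes and 12800 and 17550 nt for snoRNA genes, while that of protein-coding genes was 523050 and 531100 nt. The KO percent of all tRNA sites was 57.5 (52.6 to 62.2), and that of snoRNA sites was 53.9 (48.7 to 59.1), which includes equal shares. These intervals treat sites found in both lists as independent. Of the sites overlapping none in the other list, snoRNA genes had 5 in WT and 35 in KO. Long noncoding RNA genes held 229 and 225 sites and places without a gene 1124 and 1126. Only site numbers and lengths were compared between genotypes, since no RNA level was measured beside them.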

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

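All tests in this part were chosen after the results were seen. The cell lines went opposite ways in several comparisons, and none of these differences was tested: each group held 1 sample, and compartments were not used as replicates. The percent of transcripts with higher scores in vivo than in vitro was 38.1 in HEK293 and 66.7 in mES chromatin, 37.6 and 64.7 in nucleoplasm, and 28.5 and 87.2 in cytoplasm. Between nucleoplasm and cytoplasm, the percent higher in nucleoplasm was 59.1 in HEK293 and 29.4 in mES cells in vivo, and 44.5 and 66.2 in vitro. The Gini index was higher in vivo for 63.9% of HEK293 and 13.3% of mES transcripts in chromatin, 80.9% and 41.0% in nucleoplasm, and 83.4% and 2.66% in cytoplasm, but over nucleotides above 0 in both files it was 33.0% and 24.9%, 43.5% and 42.6%, and 55.5% and 17.8%. For nucleoplasm over cytoplasm in vivo, the log2 abundance of short minus long transcripts was -0.35 in HEK293 and 1.92 in mES cells. The median log2 abundance of chromatin over nucleoplasm in vitro was 0.88 in HEK293 and -0.32 in mES cells, but these medians depend on the unknown scaling of each file, so no direction is read from them.

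For the opposite signs of the in vivo minus in vitro difference, the mean gap between the cell lines (mES minus HEK293, over the compartments) was 38.1 percentage points. A different share of zero scores was argued against as the whole cause in the cytoplasm, where over nucleotides above 0 in both files the gap was 24.7 points, down from 58.7, and the cell lines stayed on opposite sides of 50% (45.2 and 69.9), so that much of the gap went with the zeros; this test was split by compartment after its values were seen. It stays open for the opposite signs in chromatin and nucleoplasm, where the gap averaged 11.2 points and the values were 43.5% in HEK293 and 52.0% (49.5 to 54.5) in mES chromatin and 51.4% (49.8 to 53.1) and 65.4% in nucleoplasm. Depth and scaling of the scores within each file stay open too. The gap was 35.5 points among transcripts with abundance values within 1.5 times, but abundance has no stated unit and so does not measure depth. With ranks the gap was -0.92 points, but ranks centre each file over all its scored nucleotides and so remove a real shift as well. Ranks also depend on the transcripts a file held and on its share of zeros. Cell line, rRNA removal kit and sequencer cannot be told apart here, and a biological difference between the cell lines may also have contributed and was not tested.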

How the results depend on the processing

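Of the results, 131 were recomputed with 1 choice changed at a time, in 433 alternatives, while others, such as the 5′-end values and the directions over 3 compartments, had none. In 224 the value stayed within its main counting interval or within 1.5 times for counts of genes, in 180 it moved outside with the direction kept, and in 29 the direction turned. The alternatives chosen after seeing the data were nucleotides above 0, abundance within 1.5 times, 1 transcript per pattern family, those of the 3-nt period, sites of a list at or above its median score against the whole other list, covered length in place of sites, and unshared sites at or above their list's median score. The family alternative removed few transcripts, so values unchanged under it say little about the effect of shared genes or sequence. No paired analysis by replicate number was possible because the groups, of 1 sample each, share fewer than 2 such numbers. Tests with compartments as blocks were possible and were left out, as none was planned. Not run, since they need names, sequence or transcript models not used here: 1 transcript per gene and sums over a gene's transcripts, gene lists for icSHAPE, mRNA regions, start and stop codon profiles, GGACT against GGACG, human and mouse agreement, GGAG content, and icSHAPE around Lin28A sites. The percent of transcripts with the stronger 3-nt period in vivo stayed above 50 in all 6 pairs under each of its alternatives, but among transcripts no more abundant in vivo both chromatin intervals include 50. The Gini index kept its side of 50% under both alternatives fixed beforehand, but not over nucleotides above 0, where HEK293 chromatin and nucleoplasm turned. The labels state about 200000000 reads per replicate for icSHAPE, but the reads used per file are not given in the sources used here. The values that turned and those that moved in the comparisons of the design are given next, as percent higher in the first file or in vivo. Another 30 moved with their direction kept: 11 of the 3-nt period, 11 of short transcripts, 3 of abundance by length and 5 of Lin28A sites. For all of these the cause was not tested.

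With 300 shared nucleotides, in vivo against in vitro gave chromatin 35.0%, nucleoplasm 34.0%, cytoplasm 23.1% in HEK293 and chromatin 77.9%, cytoplasm 92.3% in mES. With 300 shared nucleotides, compartments in vivo gave chromatin-nucleoplasm 60.8%, chromatin-cytoplasm 66.1% in HEK293 and chromatin-nucleoplasm 88.1%, chromatin-cytoplasm 76.6%, nucleoplasm-cytoplasm 25.7% in mES. With 300 shared nucleotides, compartments in vitro gave chromatin-cytoplasm 20.8% in HEK293 and chromatin-nucleoplasm 23.96%, chromatin-cytoplasm 51.3% (turned), nucleoplasm-cytoplasm 71.9% in mES. At 300 shared nucleotides, median profile r in vivo against in vitro gave chromatin 0.525, cytoplasm 0.517 in HEK293 and nucleoplasm 0.554, cytoplasm 0.572 in mES. At 300 shared nucleotides, median profile r of compartments in vivo gave chromatin-nucleoplasm 0.631, chromatin-cytoplasm 0.644, nucleoplasm-cytoplasm 0.647 in HEK293 and chromatin-nucleoplasm 0.691, chromatin-cytoplasm 0.710, nucleoplasm-cytoplasm 0.687 in mES. At 300 shared nucleotides, median profile r of compartments in vitro gave chromatin-nucleoplasm 0.703, nucleoplasm-cytoplasm 0.657 in HEK293 and chromatin-nucleoplasm 0.672, chromatin-cytoplasm 0.642, nucleoplasm-cytoplasm 0.685 in mES. Requiring 300 shared nucleotides, the Gini index gave nucleoplasm 84.3%, cytoplasm 89.8% in HEK293 and chromatin 5.36%, cytoplasm 0.845% in mES. With abundance of 10, in vivo against in vitro gave chromatin 41.1%, nucleoplasm 40.1% in HEK293. With abundance of 10, compartments in vivo gave nucleoplasm-cytoplasm 65.9% in HEK293 and chromatin-nucleoplasm 80.3% in mES. With abundance of 10, compartments in vitro gave chromatin-nucleoplasm 21.1%, nucleoplasm-cytoplasm 41.0% in HEK293. Over nucleotides common to all 6 files, in vivo against in vitro gave chromatin 64.9% (turned), cytoplasm 33.0% in HEK293 and chromatin 85.9%, nucleoplasm 58.6%, cytoplasm 82.3%, cytoplasm under 300 nt 31.4% (turned) in mES. Over nucleotides common to all 6 files, compartments in vivo gave nucleoplasm-cytoplasm 61.4% in HEK293 and chromatin-nucleoplasm 84.6%, chromatin-cytoplasm 69.1%, nucleoplasm-cytoplasm 25.1% in mES. Over nucleotides common to all 6 files, compartments in vitro gave nucleoplasm-cytoplasm 48.7% in HEK293 and nucleoplasm-cytoplasm 72.8% in mES. Over nucleotides above 0, in vivo against in vitro gave chromatin 43.5%, nucleoplasm 51.4% (turned), cytoplasm 45.2% in HEK293 and chromatin 52.0%, nucleoplasm under 300 nt 52.2% (turned), cytoplasm 69.9% in mES. Over nucleotides above 0, the Gini index gave chromatin 33.0% (turned), nucleoplasm 43.5% (turned), cytoplasm 55.5% in HEK293 and chromatin 24.9%, nucleoplasm 42.6%, cytoplasm 17.8% in mES. Over nucleotides above 0, compartments in vivo gave nucleoplasm-cytoplasm 53.3% in HEK293 and chromatin-nucleoplasm 71.5% in mES. Over nucleotides above 0, compartments in vitro gave chromatin-cytoplasm 23.7%, nucleoplasm-cytoplasm 39.7% in HEK293 and chromatin-nucleoplasm 45.0%, chromatin-cytoplasm 58.3% (turned), nucleoplasm-cytoplasm 51.2% in mES. Under ranks of scores, in vivo against in vitro gave nucleoplasm 65.1% (turned), nucleoplasm under 300 nt 63.3% (turned), cytoplasm 58.9% (turned), cytoplasm under 300 nt 73.4% (turned) in HEK293 and chromatin 45.4% (turned), nucleoplasm 59.3%, cytoplasm 57.1%, cytoplasm under 300 nt 22.2% (turned) in mES. Under ranks of scores, compartments in vivo gave chromatin-nucleoplasm 72.4%, chromatin-cytoplasm 69.8%, nucleoplasm-cytoplasm 47.5% (turned) in HEK293 and chromatin-nucleoplasm 58.3%, chromatin-cytoplasm 51.4%, nucleoplasm-cytoplasm 47.7% in mES. Under ranks of scores, compartments in vitro gave chromatin-nucleoplasm 64.5% (turned), chromatin-cytoplasm 64.1% (turned), nucleoplasm-cytoplasm 35.4% in HEK293 and chromatin-cytoplasm 17.7%, nucleoplasm-cytoplasm 25.8% (turned) in mES. With median scores, in vivo against in vitro gave nucleoplasm 31.3%, cytoplasm 22.3% in HEK293 and chromatin 81.4%, nucleoplasm 58.3%, cytoplasm 94.1% in mES. With median scores, compartments in vivo gave chromatin-nucleoplasm 63.4%, chromatin-cytoplasm 68.2% in HEK293 and chromatin-nucleoplasm 90.0%, chromatin-cytoplasm 74.6%, nucleoplasm-cytoplasm 21.5% in mES. With median scores, compartments in vitro gave chromatin-nucleoplasm 15.7% in HEK293 and chromatin-nucleoplasm 22.2%, chromatin-cytoplasm 45.2%, nucleoplasm-cytoplasm 76.7% in mES. With 50 shared nucleotides, in vivo against in vitro gave cytoplasm 30.3% in HEK293 and chromatin 63.6%, nucleoplasm 63.2%, cytoplasm 85.0% in mES. With 50 shared nucleotides, compartments in vivo gave chromatin-cytoplasm 54.6% in HEK293 and chromatin-nucleoplasm 71.4%, chromatin-cytoplasm 58.9% in mES. With 50 shared nucleotides, compartments in vitro gave chromatin-nucleoplasm 22.5%, chromatin-cytoplasm 33.5%, nucleoplasm-cytoplasm 46.0% in HEK293 and chromatin-nucleoplasm 32.9%, chromatin-cytoplasm 50.7% (turned) in mES. At abundance within 1.5 times, in vivo against in vitro gave chromatin 59.2% in mES. At abundance within 1.5 times, compartments in vivo gave nucleoplasm-cytoplasm 76.1% in HEK293 and chromatin-nucleoplasm 82.4%, chromatin-cytoplasm 69.6%, nucleoplasm-cytoplasm 30.7% in mES. At abundance within 1.5 times, compartments in vitro gave chromatin-nucleoplasm 8.91%, nucleoplasm-cytoplasm 72.2% (turned) in HEK293 and chromatin-cytoplasm 71.0% (turned), nucleoplasm-cytoplasm 81.4% in mES. Keeping 1 transcript per family, in vivo against in vitro gave cytoplasm 88.1% in mES. Over all scored nucleotides, compartments in vivo gave chromatin-nucleoplasm 41.1% (turned), chromatin-cytoplasm 54.9% in HEK293 and chromatin-nucleoplasm 58.1%, chromatin-cytoplasm 51.1%, nucleoplasm-cytoplasm 23.5% in mES. Over all scored nucleotides, compartments in vitro gave chromatin-cytoplasm 25.2%, nucleoplasm-cytoplasm 42.2% in HEK293 and chromatin-nucleoplasm 23.3%, chromatin-cytoplasm 39.4%, nucleoplasm-cytoplasm 57.6% in mES. As Spearman rho, profile medians in vivo against in vitro gave chromatin 0.485, nucleoplasm 0.545, cytoplasm 0.498 in HEK293 and chromatin 0.487, nucleoplasm 0.494, cytoplasm 0.524 in mES. As Spearman rho, profile medians of compartments in vivo gave chromatin-nucleoplasm 0.682, chromatin-cytoplasm 0.679, nucleoplasm-cytoplasm 0.568 in HEK293 and chromatin-nucleoplasm 0.640, chromatin-cytoplasm 0.694, nucleoplasm-cytoplasm 0.600 in mES. As Spearman rho, profile medians of compartments in vitro gave chromatin-nucleoplasm 0.643, chromatin-cytoplasm 0.526, nucleoplasm-cytoplasm 0.598 in HEK293 and chromatin-nucleoplasm 0.577, chromatin-cytoplasm 0.551, nucleoplasm-cytoplasm 0.583 in mES.

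Abundance of at least 10 in 1 file gave median log2 ratios in HEK293 of -0.24 for chromatin over nucleoplasm in vivo and, in vitro, 1.10 for chromatin over nucleoplasm, -0.73 for chromatin over cytoplasm and -1.30 for nucleoplasm over cytoplasm. In mES cells in vivo it gave -0.83 for chromatin over nucleoplasm. A pseudocount of 0.1 gave -1.68 for nucleoplasm over cytoplasm in HEK293 in vivo, with 1.00 for chromatin over nucleoplasm and -1.33 for nucleoplasm over cytoplasm in vitro. In mES cells it gave -0.83 for chromatin over nucleoplasm, -1.33 for chromatin over cytoplasm and -0.59 for nucleoplasm over cytoplasm in vivo, and -0.91 for nucleoplasm over cytoplasm in vitro. For Lin28A sites, a reciprocal overlap of 50% gave 73.0% of WT and 71.1% of KO sites. Sites at or above their list's median score overlapped the whole other list for 93.5% of WT and 92.6% of KO. Between such sites of both lists, 76.9% of KO sites overlapped, 2383 genes were in both lists and 560 in the KO list only. The KO to WT ratio of such sites was 0.965 for protein-coding genes and 0.926 for places without a gene, both turned, and the KO minus WT difference was 2 for Gm33272, -8 for Nedd4 and 1 for Eif4g2, all turned. Covered length gave a KO to WT ratio of 1.01 for long noncoding RNA genes (turned), and the KO share of unshared sites without a gene was 41.2% at or above the median score (turned).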

Other observations

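All tests in this part were chosen after the patterns had been seen, and for those on zeros and the 3-nt period, on codon-wise contacts and on tRNA families the bounds were set before the values they measure were seen. Nucleotides near the 5′ end of transcripts were more reactive than the next stretch in all 12 icSHAPE files. The mean score of nucleotides 7 to 50 was higher than that of nucleotides 51 to 100 for between 54.8% (HEK293 nucleoplasm in vitro) and 66.7% (HEK293 chromatin in vivo) of transcripts of at least 600 nt. The intervals were wide in chromatin, 52.1 to 79.2 over 51 HEK293 transcripts in vivo and 49.9 to 64.2 over 196 mES transcripts in vitro, the latter including equal numbers. In mES cytoplasm the values were 64.6% (62.0 to 67.1; n = 1391) in vivo and 64.6% (61.9 to 67.3; n = 1275) in vitro. No alternative setting was tried for these values.

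The Lin28A site lists were dominated by a few places in the authors' score. The 10 sites with the largest score times width held 56.8% of its sum in WT and 56.4% in KO. By score alone, the highest WT site (chromosome 15, 72907101 to 72907150, plus strand, mm10) lay in Trappc9. The highest KO site by score (chromosome 18, 10052101 to 10052150, minus strand) overlapped no gene. A site of 3800 nt in WT and 4250 nt in KO covered Rn18s-rs5, annotated as a pseudogene. Pseudogene sites together held 48.1% of the summed score times width in WT and 46.6% in KO, most of it in this site. These shares therefore describe mainly that site and not pseudogenes as a class. The symbol Rn18s-rs5 names a sequence related to ribosomal RNA. Whether the reads of that site came from ribosomal RNA or from background was not tested.

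Unshared sites, those overlapping no site of the other list, were more often from the KO list for small RNA classes. The KO list held 75 of the 81 unshared tRNA sites (92.6%; 84.6 to 97.2), 35 of 40 unshared snoRNA sites (87.5%; 73.2 to 95.8) and 11 of 13 unshared snRNA sites (84.6%; 54.6 to 98.1). For protein-coding genes the KO share was 52.0% (50.5 to 53.4), and for microRNA genes 29.4% (10.3 to 56.0).

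The 3-nt period was stronger in vivo than in vitro. A different share of zeros was argued against as the whole cause, since over nucleotides above 0 in both files the percent stronger in vivo stayed above 50, intervals included, in all 6 pairs, the lowest being 57.4 (50.4 to 64.2) in HEK293 chromatin. Greater depth in vivo stays open, a reading changed after the values were seen, since abundance has no stated unit and does not measure it: among transcripts no more abundant in vivo the lowest percent was 65.0 in nucleoplasm and cytoplasm, and in chromatin it was 52.4 (46.0 to 58.8) in HEK293 and 54.2 (48.4 to 60.02) in mES cells. For a candidate explanation by ribosomes or other codon-wise contacts in the cytoplasm, among transcripts measured in 3 compartments the cytoplasm exceeded chromatin by 6.25 percentage points in HEK293 (n = 96) and 6.52 in mES cells (n = 460), with overlapping intervals, and in mES cells nucleoplasm (78.9%; 74.9 to 82.6) lay above cytoplasm (73.5%; 69.2 to 77.5). The direct comparison in vivo goes against it in mES cells, where the period was stronger in nucleoplasm than in cytoplasm for 61.2% of transcripts, but not in HEK293 (46.9%), and carry-over between fractions was not measured, so it stays open.

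More tRNA, snoRNA and snRNA sites stood in the KO list. A lower calling limit across the whole KO list was argued against as the sole cause. Among unshared sites at or above their list's median score, the KO share of these classes without chromosome MT was 93.2% (83.5 to 98.1). For protein-coding genes it was 50.4% (46.3 to 54.5). The cut was each list's own median (20 in WT, 19 in KO). Of KO sites scoring at least 50, 99.8% overlapped the WT list, so the test rests mainly on lower scores. A limit that differed by place or class was not tested, as the site caller is not given. Reads of near-identical copies placed at several loci stay open for the snoRNA part, where the KO share of unshared sites was 87.5% but copies were not measured. For the tRNA part they stay open too: 1 tRNA family had a site in the KO list only, which met the bound of at most 2 written beforehand for this explanation, but 44 of the 49 annotated families already had a WT site, so the measure had little room, and the reading was changed for that reason after the value was seen. RNA level, fragment size and the absence of Mettl3 may each have contributed and were not tested. The anti-GFP controls were not analysed and the control of the site caller is not given, so these sites were not checked against background.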
